A study of Escherichia coli with 21 samples.

How the data were processed

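Total RNA of E. coli ATCC 8739 was depleted of ribosomal RNA and made into directional libraries, per the labels' protocols. The deposited table gave FPKM, fragments scaled by gene length and by library, computed by the authors for each library and gene. Per the submitters' processing notes, the tools used were fastp, Bowtie2, featureCounts and DESeq2, and their roles, versions and parameters are not given in the sources used here. The genome build is not given in the sources used here beyond a chromosome name in the table. Whether counting used the strand is not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. The table held 4954 genes, of which 3923 carried a symbol and 343 were unannotated regions.

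The depth was recovered from the values. FPKM times gene length came out as whole multiples of 1 step per library for 100% of values above 0 in every library, within a tolerance of 0.05 of a step, and gave 704174 to 8368765 reads per library. Over the tested genes the median-of-ratios factor was 0.993 in every library, as in values scaled by such factors and not by each library's own reads. FPKM times gene length, summed and set against the sum that scaling by own reads gives, ran from 0.749 to 7.68. Genes with near-identical copies had low values, such as gadB at 7.41 and the rrf copy at 3.21 FPKM in control libraries, and are uncertain. Recovered reads of replicates differed beyond sampling noise in every pair, with a chi-square per degree of freedom of 2.56 to 983 over genes with at least 10 reads, so no library was counted as a duplicate.

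Groups were taken from the sample labels, and no sample was left out. Values were transformed to log2(FPKM + 1), so fold changes understate changes of low genes. Genes with at least 1 FPKM in at least 3 of the 21 libraries were kept, 4908 genes, and 46 were not tested. All 7 groups entered 1 fit in limma 3.58.1 (R 4.3.3) with a mean per group, no block and a trended prior, and two-sided p-values were adjusted by Benjamini-Hochberg at 0.05. This fit shares 1 estimate of spread per gene between groups, although the spread differed between groups. Changes of at least 2-fold (1 on the log2 scale) were counted beside the calls. The 12 comparisons set each treatment against control, the intensities of each technology against each other, and the technologies against each other as means of their 2 groups.

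The 32 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists in a comparison, and again with an estimated correlation and with fry. Lists needed at least 4 tested members. Members were matched by symbol, and older symbols through a reference table of E. coli K-12 genes, used for names only. The flagella list matched 62 genes for 46 symbols, since some symbols stand at several loci of the table, and the stable RNA list matched 4 of 26. For each treatment the text names the 8 largest rises and 8 largest falls among genes with a symbol that passed and whose 3 treated libraries lay outside the control range, and the 2 members of each called list farthest in its direction. For the other comparisons it names 5 and 5, and where fewer than 3 genes qualified, the 5 with the smallest p. rnpB and ssrA, members of the stable RNA list, were named after their values were seen. The rules, lists, gene and list tests and all but 2 of the alternative settings below were fixed before the data were examined. Most tests of explanations at the end were chosen after the results were seen.

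The test was checked on simulated data with known answers. Reads were drawn for the 4908 tested genes with the control means, the real depths and the residual spread, and 200 genes were changed in the 72 °C group. For 72 °C against control, 51% of the 100 genes changed 2-fold and 80% of the 100 changed 4-fold were recovered, with 9 false calls among 140. The simulation gave every group the same spread, which the real groups do not have.

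The alternative settings were pseudocounts of 0.25 and 5, no filter, a mean of at least 10 FPKM, median-of-ratios rescaling, quantile normalization, only the compared groups in the fit, a replicate block, library weights by arrayWeights, a 2-fold minimum, voom on the recovered reads, and leaving out each replicate in turn. The default method of arrayWeights did not converge, so its gene-by-gene method was used. Added after seeing the data were scaling to each library's own reads and leaving out 4 libraries, the one of lowest mean correlation with its group in each group where that was below 0.95: 60 °C replicate 1, 300 MPa replicate 2, 50 kJ/kg replicate 3 and 70 kJ/kg replicate 1. Unchanged groups against shared controls were simulated 100 times by redrawing library deviations with random signs around the mean of all libraries.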

Results

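RNA sequencing measured the transcripts of Escherichia coli ATCC 8739, a strain used in tests of preservatives, after inoculation in strawberry nectar. The 21 libraries fell into 7 groups of 3 replicates: a control, heating at 60 °C for 200 s, heating at 72 °C for 50 s, high pressure of 300 MPa for 3 min, high pressure of 400 MPa for 1 min, and pulsed electric fields of 6 kV/cm at 50 kJ/kg or at 70 kJ/kg. The labels did not say that replicates came from separate cultures, so p-values measured only the spread between these libraries, which may be technical. Reads recovered from the deposited values ranged from 704174 in 60 °C replicate 1 to 8368765 in the 50 kJ/kg replicate 3, with a median of 107 reads per gene in the shallowest library and 1466 in control replicate 3. The comparisons asked how 3 preservation technologies, each at 2 intensities, affected the transcriptome. Each gene named as risen or fallen in a treatment, other than members of gene lists, had all 3 treated libraries on 1 side of the 3 control libraries.

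Most genes lay close to 1 level in most libraries. In control replicate 1 the median gene had 171 FPKM with quartiles of 133 and 219, and 90.6% of genes lay within 2-fold of that median. The lowest such share was 51.8% in the 50 kJ/kg replicate 3. The ribosomal protein genes, normally among the most abundant transcripts, had a median of 207, 154 and 204 FPKM in the control libraries, against 149, 153 and 149 FPKM for the curli and biofilm matrix genes. The RNA of RNase P, rnpB, took 1.71, 0.545 and 1.56% of recovered reads in the control libraries. It took 10.3, 25.3 and 48.1% at 50 kJ/kg, and 39.6, 6.73 and 3.29% at 70 kJ/kg. Replicates of some groups differed widely: 60 °C replicate 1 correlated at 0.690 and 0.660 (Pearson, across genes, which are not independent replicates) with the other replicates of its group, which correlated at 0.977 with each other.

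**Figure D1:**
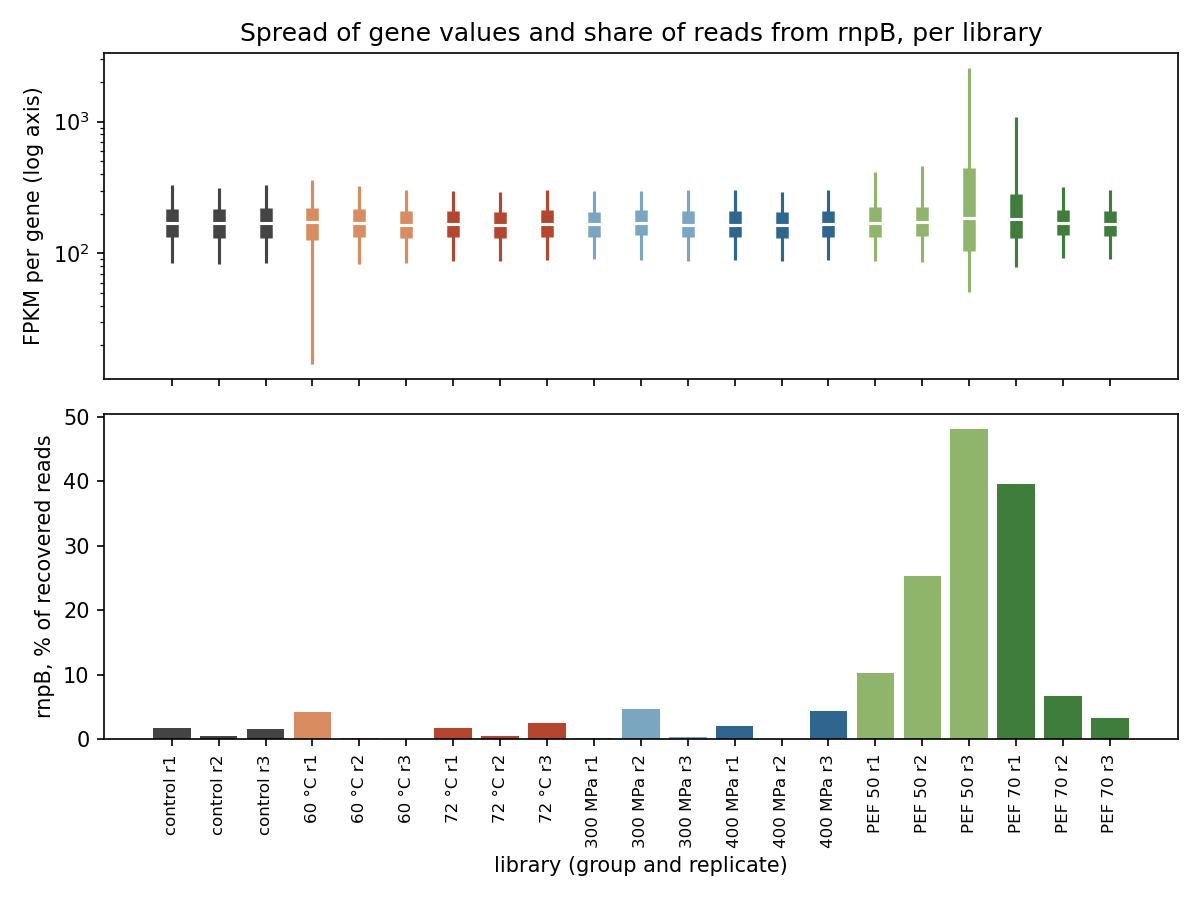
The upper panel shows FPKM per gene on a log axis for each of the 21 libraries (white mark, median; thick bar, quartiles; thin line, 5th to 95th percentile; genes of at least 300 bases), and the lower panel the percentage of recovered reads from rnpB. The medians lay between 163 and 185 FPKM, and rnpB reached 48.1% in the 50 kJ/kg replicate 3.

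After heating at 60 °C the largest rise of a named gene was in phnC, which encodes the ATPase of the phosphonate transporter (D9Q99_RS20680, positions 4304875 to 4305663 of the chromosome sequence that the deposited table names). It rose from 47.5 ± 0.783 FPKM in control libraries to 119.5 ± 34.7 FPKM (SD, n = 3; log2 fold change 1.28 ± 0.20 (SE), adjusted p = 0.00232). The phosphonate genes phnL (1.17), phnI (0.95) and phnJ (0.80) rose too, on the log2 scale. So did the hydrogenase maturation gene hypC (1.00), the fimbrial chaperone gene ecpB (0.88), the nickel transporter gene nikB (0.87) and ygaH (0.84). The O-antigen flippase gene wzx had the largest fall of a named gene (log2 fold change -3.16 ± 0.89 (SE), adjusted p = 0.0450). Also lower were the prophage gene rzpQ (-1.72), yqeK (-1.72), gnsB (-1.67), flxA (-1.57), the quorum-sensing regulator gene sdiA (-1.34), ymdF (-1.33) and the toxin gene hokA (-1.29). Without 60 °C replicate 1, the shallowest library, wzx was at -1.61, rzpQ at -0.93, flxA at -0.87 and sdiA at -0.64, and wzx and flxA no longer passed (adjusted p = 0.0520 and 0.0544). Of the 17 genes named for 60 °C that passed, 7, 7 and 6 still passed without control replicate 1, 2 or 3 and 12, 16 and 16 without 60 °C replicate 1, 2 or 3.

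Of 20 toxin-antitoxin genes, 2 fell and 0 rose at 60 °C over all genes tested, with 0 higher and 8 lower adjusted over the list alone. The list had adjusted p = 0.00911 with the preset correlation and adjusted p = 0.608 with an estimated correlation. The antitoxin genes relB (-2.48 ± 1.02 SE, adjusted p = 0.147) and mazE (-1.32 ± 0.44 SE, adjusted p = 0.0841) had the lowest values in this list and did not pass; without 60 °C replicate 1 relB was at -0.49 and mazE at -0.50. Among 36 genes of anaerobic metabolism, 3 rose, including hycB of formate hydrogenlyase (0.75), with 3 higher and 0 lower adjusted over the list alone. This list had adjusted p = 0.0452 with the preset correlation and adjusted p = 0.608 with an estimated correlation, and nirC was at 0.64 without passing. The 33 iron uptake genes lay higher as a list, with adjusted p = 0.0452 with the preset correlation and adjusted p = 0.947 with an estimated correlation. Of them 0 passed, with 0 higher and 0 lower adjusted over the list alone, and the highest values were those of ybdZ (0.80) and fecC (0.70). Of these 3 list calls, 1 held without control replicate 2 or without 60 °C replicate 2, and 2 without control replicate 3 or without 60 °C replicate 1 or 3. In this comparison 310 of 4908 tested genes passed limma's test at the adjusted threshold, 134 higher and 176 lower. Of these, 46 changed at least 2-fold. Counts moved to 77, 74 and 71 without control replicates 1, 2 and 3 and 478 without 60 °C replicate 3. The count was 2449 without the 4 libraries least like their groups, 848 after quantile normalization and 0 with scaling to each library's own reads. All 3 heated libraries lay outside the control range for 2261 genes, where chance gives 10% on average. Genes are not independent, so a single chance order of the libraries can give more.

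After heating at 72 °C raiA, which encodes a ribosome-associated inhibitor of translation, fell from 1473 ± 794 to 146 ± 39.6 FPKM (SD, n = 3; positions 1174584 to 1174934; log2 fold change -3.16 ± 0.59 (SE), adjusted p = 0.0205). The heated value was within 2-fold of these libraries' medians of 164 to 168 FPKM, the level of most genes. With a single library left out, raiA passed only without control replicate 2. The other large falls were in the leader peptide gene of the envelope stress operon, rseD (log2 fold change -0.94 ± 0.16 (SE), adjusted p = 0.0114), and in the small membrane protein gene blr (-0.82), the galactitol transporter gene gatA (-0.78), ariR (-0.77), ymgA (-0.76), the ribosomal protein gene rplY (-0.72) and the gyrase inhibitor gene sbmC (-0.70). phnC rose (log2 fold change 1.05 ± 0.20 (SE), adjusted p = 0.0205). ygaH (0.78), nikB (0.67), the efflux gene mdtN (0.64), the citrate lyase gene citF (0.62), thiP (0.57), rcsF (0.50) and yjbF (0.49) rose as well. Of 17 genes of the peroxide response, 0 passed over all genes tested, with 0 higher and 1 lower adjusted over the list alone. The list had adjusted p = 0.0288 with the preset correlation and adjusted p = 0.9502 with an estimated correlation. In this list dps, which encodes a DNA-binding protein of stationary phase, was at 207 against 2655 FPKM (-3.45 ± 0.87 SE, adjusted p = 0.0645), and ahpC was at -2.82 ± 1.19 (SE, adjusted p = 0.298). Of 20 toxin-antitoxin genes, 1 fell, the antitoxin gene yafN (-0.66), with 0 higher and 5 lower adjusted over the list alone. That list had adjusted p = 0.0288 with the preset correlation and adjusted p = 0.767 with an estimated correlation, and mqsR was at -0.59 without passing. Of these 2 list calls 0 held without control replicate 1, control replicate 3 or 72 °C replicate 2, and 1 without 72 °C replicate 3.

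At 72 °C 65 of 4908 tested genes passed limma's test at the adjusted threshold, 25 higher and 40 lower. Of these, 3 changed at least 2-fold. The number called was 6, 13 and 5 without control replicates 1, 2 and 3 and 8, 15 and 2 without 72 °C replicates 1, 2 and 3. Of the 17 genes named for 72 °C that passed, 2, 5 and 3 still passed without control replicate 1, 2 or 3 and 4, 5 and 1 without 72 °C replicate 1, 2 or 3. The count was 2619 when only the compared groups entered the fit, 2132 without the 4 libraries least like their groups, 219 higher and 150 lower after quantile normalization and 0 with scaling to each library's own reads. The heated libraries lay outside the control range for 3030 genes, where chance gives 10% on average. Genes move together, so a chance order of the libraries can exceed that. Between 72 and 60 °C limma called 0 of 4908 genes, against 195 at an unadjusted p under 0.05 and 0 by voom. The smallest p-values belonged to yehE (0.52 ± 0.15 SE), tsaA (-0.28 ± 0.08 SE), ynfU (0.94 ± 0.29 SE), rhsC (0.47 ± 0.15 SE) and chiQ (0.55 ± 0.17 SE), all at adjusted p = 0.873. Camera called 5 lists here, among them ribosomal proteins (lower, median -0.44), with an adjusted p = 0.908 with an estimated correlation for each. Library weights gave 544 genes for this pair.

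After high pressure of 300 MPa raiA fell from 1473 ± 794 to 155 ± 21.2 FPKM (SD, n = 3; log2 fold change -3.05 ± 0.59 (SE), adjusted p = 0.0195). The treated value again lay within 2-fold of the library medians. With a single library left out, raiA passed only without control replicate 2. ymdF (-1.60), rseD (-1.06), yegR (-0.999), the phage shock gene pspA (-0.91), rhsC (-0.79), the ribosome rescue gene arfA (-0.78) and ymgA (-0.75) also fell. phnC rose (log2 fold change 1.04 ± 0.20 (SE), adjusted p = 0.0195). ygaH (0.85), mdtN (0.64), rcsF (0.62), citF (0.59), the secretion gene gspK (0.54), gfcC (0.50) and thiP (0.49) rose as well. None of the 32 gene lists passed by camera at 300 MPa, the smallest adjusted p being 0.0891 for the toxin-antitoxin list, with 0 higher and 3 lower adjusted over the list alone. At 300 MPa 64 of 4908 tested genes passed limma's test at the adjusted threshold, 24 higher and 40 lower. Of these, 7 changed at least 2-fold. The count became 8, 19 and 6 without control replicates 1, 2 and 3 and 11, 16 and 8 without 300 MPa replicates 1, 2 and 3. Of the 16 genes named for 300 MPa that passed, 4, 9 and 3 still passed without control replicate 1, 2 or 3 and 4, 5 and 3 without 300 MPa replicate 1, 2 or 3. The count was 1241 with only the compared groups, 1873 without the 4 libraries least like their groups, 156 higher and 134 lower after quantile normalization and 0 with scaling to each library's own reads.

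After high pressure of 400 MPa raiA fell from 1473 ± 794 to 131 ± 24.0 FPKM (SD, n = 3; log2 fold change -3.30 ± 0.59 (SE), adjusted p = 0.0141). The treated value lay within 2-fold of the library medians here too. With a single library left out, raiA passed only without control replicate 2. Falls were also seen in rseD (-1.09), pspA (-0.80), yafN (-0.79), gatA (-0.76), rplY (-0.75), blr (-0.75) and arfA (-0.72). The largest rise of a named gene was that of ygaH (log2 fold change 0.90 ± 0.12 (SE), adjusted p = 0.00398), followed by phnC (0.89), gfcC (0.62), citF (0.59), hyuA (0.46), yjbF (0.44) and the helicase gene lhr (0.35). Of 17 peroxide response genes 0 passed over all genes tested, with 0 higher and 1 lower adjusted over the list alone. The list had adjusted p = 0.00394 with the preset correlation and adjusted p = 0.968 with an estimated correlation, and dps (-3.56 ± 0.87 SE, adjusted p = 0.0621) and ahpC (-3.08 ± 1.19 SE, adjusted p = 0.262) had its lowest values. At 400 MPa 59 of 4908 tested genes passed limma's test at the adjusted threshold, 17 higher and 42 lower. Of these, 6 changed at least 2-fold. It moved to 10, 19 and 7 without control replicates 1, 2 and 3 and 6, 7 and 13 without 400 MPa replicates 1, 2 and 3. Of the 15 genes named for 400 MPa that passed, 4, 7 and 4 still passed without control replicate 1, 2 or 3 and 4, 4 and 5 without 400 MPa replicate 1, 2 or 3. The count was 2537 with only the compared groups, 2100 without the 4 libraries least like their groups, 169 higher and 128 lower after quantile normalization and 0 with scaling to each library's own reads. Between 400 and 300 MPa limma called 0 of 4908 genes, against 8 at an unadjusted p under 0.05 and 0 by voom. The smallest p-values there belonged to ycaR (-0.47 ± 0.17 SE), rcsF (-0.27 ± 0.11 SE), yidG (-0.32 ± 0.14 SE), envC (0.23 ± 0.11 SE) and rpsR (-0.45 ± 0.21 SE), each with an adjusted p of 1. Camera called 5 lists, among them ribosomal proteins (lower at 400 MPa, median -0.22), with an adjusted p = 0.939 with an estimated correlation for each.

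**Figure D2:**
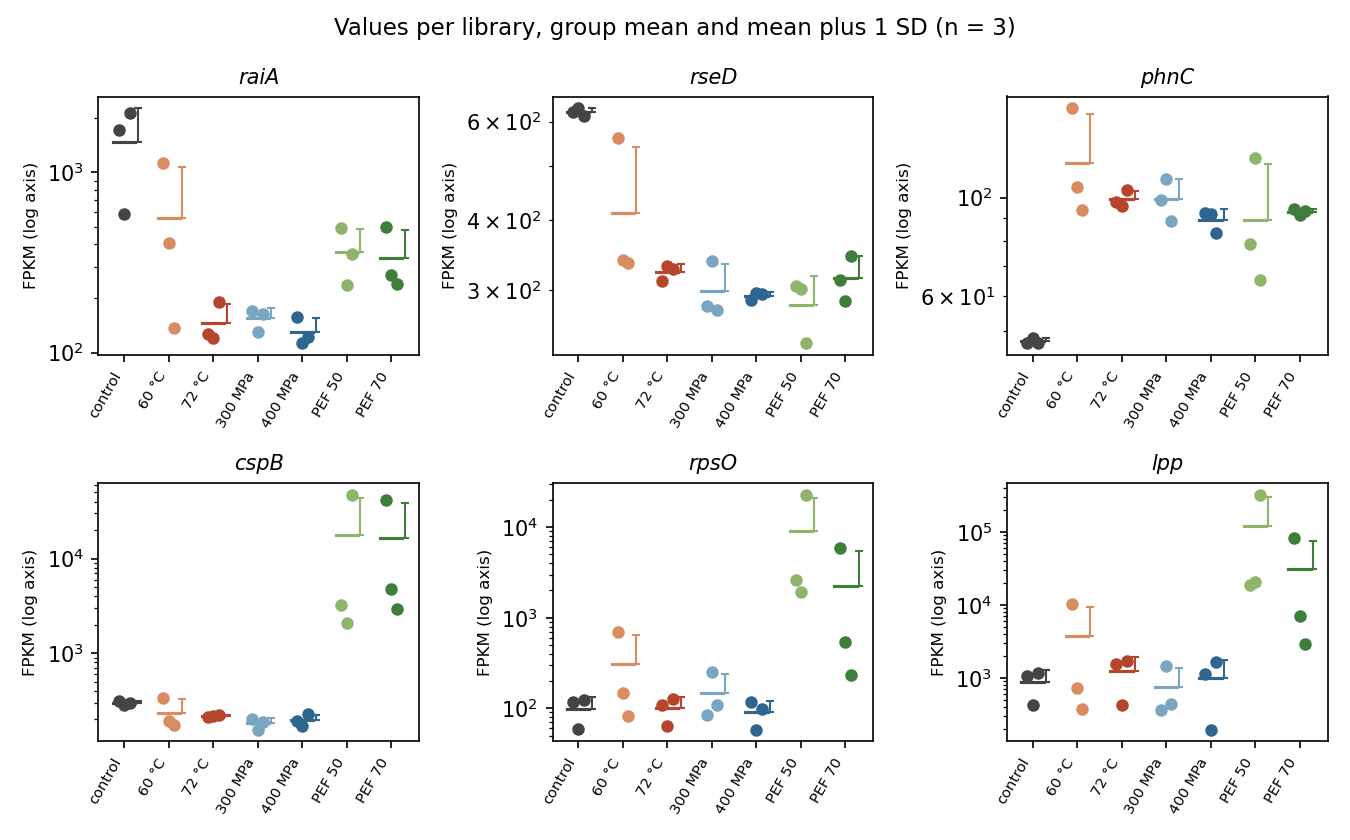
Each point is one library's FPKM on a log axis, the horizontal line is the group mean and the bar reaches 1 SD above it (n = 3 per group); only the upper SD is drawn because the lower one falls below 0 in some groups. By group mean, raiA and rseD were highest in the control libraries and phnC lowest there, while cspB, rpsO and lpp were highest after pulsed electric fields, with lpp at 121251 ± 175891 FPKM at 50 kJ/kg, a mean carried by replicate 3.

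After the pulsed electric field of 50 kJ/kg the murein lipoprotein gene lpp rose from 886 ± 405 to 121251 ± 175891 FPKM (SD, n = 3; positions 2158986 to 2159222; log2 fold change 5.95 ± 1.43 (SE), adjusted p = 0.00945). Replicate 3 carried that mean: without it lpp was at 19702 ± 1291 FPKM (SD, n = 2), with a log2 fold change of 4.60 (adjusted p = 0.0490). The ribosomal protein genes rpsO (5.67), rpsU (4.92) and rpmJ (4.79), ymcF (5.26), cspE (4.95), the cold shock helicase gene deaD (4.88) and the lipoprotein gene nlpI (4.91) followed on the log2 scale. A 5S ribosomal RNA copy, rrf, was listed at 0 in all 3 treated libraries, and is uncertain because near-identical copies share its reads. Other named genes that fell were raiA (-1.89), dicC (-1.50), yqeK (-1.49), yegR (-1.47), yccE (-1.44), ypaB (-1.43) and iraM (-1.38). Without 50 kJ/kg replicate 3 ymcF was at 2.92 and dicC at -0.94, and dicC no longer passed (adjusted p = 0.244). rnpB took 10.3 to 48.1% of reads in these libraries, against 0.545 to 1.71% in control libraries. In all, 1673 of 4908 tested genes passed limma's test at the adjusted threshold, 879 higher and 794 lower. Of these, 642 changed at least 2-fold, 559 of them higher.

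Several lists rose at 50 kJ/kg, where rnpB took up to 48.1% of reads. 42 of 54 ribosomal protein genes rose (44 adjusted over the list alone; adjusted p = 6.02e-11), while 1 fell. 9 of 12 cold shock genes rose (11 adjusted over the list alone; adjusted p = 5.67e-04), with deaD at 4.88 and cspA at 4.77 and 1 that fell. 14 of 21 heat shock genes rose (16 adjusted over the list alone; adjusted p = 1.38e-05), with the protease subunit gene clpX at 4.36 and the sigma factor gene rpoH at 4.01. Of the sigma E envelope stress list, 13 of 18 genes rose (14 adjusted over the list alone; adjusted p = 3.01e-05), with rpoH at 4.01 and bamC at 3.60. Of the CpxAR list, 9 of 14 genes rose (10 adjusted over the list alone; adjusted p = 7.23e-04), with the proteases htpX at 3.96 and degP at 2.65. 10 of 17 peroxide response genes rose (12 adjusted over the list alone; adjusted p = 1.22e-04), with fur at 3.91 and ahpF at 3.22. Of the superoxide and redox-drug list, 12 of 20 genes rose (14 adjusted over the list alone; adjusted p = 4.79e-05), with sodA at 2.62 and acrB at 2.35. Without 50 kJ/kg replicate 3 bamC was at 2.36 and acrB at 1.31, and neither passed (adjusted p = 0.0665 and 0.116). With an estimated correlation, every list called at 50 kJ/kg had an adjusted p between 0.522 and 0.623, so none of these list calls held there.

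Metabolic and envelope lists also moved at 50 kJ/kg, where 879 of all 4908 tested genes rose and 794 fell. 12 of 34 respiratory chain and ATP synthase genes rose (20 adjusted over the list alone; adjusted p = 1.26e-05), with atpC at 3.39 and cyoE at 2.92. 3 of 13 tricarboxylic acid cycle genes rose (1 adjusted over the list alone; adjusted p = 0.0254), with sucA at 2.67, and sucC at 2.13 did not pass. 5 of 20 sugar uptake and glycolysis genes rose (5 adjusted over the list alone; adjusted p = 9.07e-04), with the glucose transporter gene ptsG at 2.97, and fruB at 2.46 did not pass. 13 of 33 iron uptake genes rose (18 adjusted over the list alone; adjusted p = 0.00329), with fhuA at 2.95 and exbD at 2.81 and 1 that fell. 13 of 23 fatty acid and phospholipid synthesis genes rose (17 adjusted over the list alone; adjusted p = 1.55e-05), with accC at 3.76 and fabZ at 2.83. 15 of 27 sulfate assimilation and cysteine genes rose (15 adjusted over the list alone; adjusted p = 0.00329), with cysA at 3.55 and cysK at 3.43 and 2 that fell. 8 of 16 genes of the arginine list rose (9 adjusted over the list alone; adjusted p = 0.0125), with artM at 1.68 and carB at 1.47 and 1 that fell. 6 of 8 histidine synthesis genes rose (7 adjusted over the list alone; adjusted p = 0.00329), with hisD at 2.68 and hisG at 1.81. Other lists fell. 8 of 22 acid resistance genes fell (8 adjusted over the list alone; adjusted p = 0.00820), with hdeA at -1.31 and gadX at -0.97. 7 of 20 toxin-antitoxin genes fell (7 adjusted over the list alone; adjusted p = 0.00544), with yafN at -1.13 and mqsA at -0.87. 6 of 16 curli and biofilm genes fell (8 adjusted over the list alone; adjusted p = 0.0287), with csgD at -0.77 and csgB at -0.73. 9 of 62 flagella and chemotaxis genes fell (8 adjusted over the list alone; adjusted p = 0.0101), with flgB at -0.91 and fliE at -0.79 not passing. That share of fallen genes was below the share over all tested genes. The values of many of these genes moved by over 1.5 times without 50 kJ/kg replicate 3, where atpC was at 1.76, cyoE at 1.46, sucA at 1.23, sucC at 0.83, ptsG at 1.55, fruB at 0.98, exbD at 1.74, fabZ at 1.68, artM at 0.68, carB at 0.79, hisD at 1.76, hisG at 1.07, hdeA at -0.80, mqsA at -0.54 and csgD at -0.49. Of these, genes that no longer passed were atpC (adjusted p = 0.219), cyoE (adjusted p = 0.241), sucA (adjusted p = 0.255), ptsG (adjusted p = 0.146), exbD (adjusted p = 0.0930), fabZ (adjusted p = 0.101), artM (adjusted p = 0.316), carB (adjusted p = 0.127), hisG (adjusted p = 0.0617) and csgD (adjusted p = 0.168). Without that library 15 of 19 list calls at 50 kJ/kg held, and those lost were acid resistance (adjusted p = 0.0766), the tricarboxylic acid cycle (adjusted p = 0.119), flagella and chemotaxis (adjusted p = 0.115) and curli and biofilm (adjusted p = 0.119). These lists too had adjusted p-values of 0.522 to 0.623 with an estimated correlation.

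With only the control and 50 kJ/kg libraries in the fit, which changes both the spread and the residual degrees of freedom, the 50 kJ/kg count was 1. The number of calls was 813, 656 and 785 without control replicates 1, 2 and 3 and 2703 and 638 without 50 kJ/kg replicates 1 and 3. Of the 46 genes named for 50 kJ/kg that passed, 34, 30 and 33 still passed without control replicate 1, 2 or 3 and 46, 45 and 24 without 50 kJ/kg replicate 1, 2 or 3. The count was 2850 without the 4 libraries least like their groups, and 205 higher and 3211 lower with scaling to each library's own reads, which moved the median gene by -1.54 on the log2 scale. The 3 libraries lay outside the control range for 2762 genes, where chance gives 10% on average. Genes move together, so a chance order of these libraries can exceed that.

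After 70 kJ/kg the cold shock gene cspB rose from 298 ± 13.8 to 16505 ± 21928 FPKM (SD, n = 3; positions 2281202 to 2281417; log2 fold change 4.81 ± 0.94 (SE), adjusted p = 0.0304). Replicate 1 carried that mean: without it cspB was at 3855 ± 1291 FPKM (SD, n = 2), with a log2 fold change of 3.65 (adjusted p = 0.118), and did not pass. phnC (0.96) and ygaH (0.62) rose. Named genes that fell were rseD (log2 fold change -0.99 ± 0.16 (SE), adjusted p = 0.0235), yafN (-0.80), arfA (-0.71), yggM (-0.59), frwB (-0.59), yncJ (-0.58), yajD (-0.57) and yejG (-0.56). Among cold shock genes 1 of 12 passed, with 3 higher and 1 lower adjusted over the list alone, and deaD was at 3.35 (2.02 without 70 kJ/kg replicate 1). Of 54 ribosomal protein genes 0 passed, with 0 higher and 1 lower adjusted over the list alone, and their median was 1.27. Camera called 13 lists at 70 kJ/kg, 11 higher and 2 lower, with adjusted p up to 0.0379, and each had an adjusted p = 0.717 with an estimated correlation. Of these 13 list calls 0 held without 70 kJ/kg replicate 1, and the mean log2 fold change went from 0.86 to 0.02 for heat shock, from 0.68 to -2.65e-04 for sigma E, from 0.28 to -0.05 for superoxide, from 0.51 to -0.03 for sugar uptake and from 1.26 to 0.30 for ribosomal proteins; relative to the other genes the first 4 turned direction. Of the 13, 9 held without control replicate 2 and 12 without control replicate 3. Brackets below give values without 70 kJ/kg replicate 1. The list members named next passed neither over all genes tested nor adjusted over their list alone. Of respiratory chain genes atpC was at 2.28 (0.88) and nuoG at 2.03 (0.83), and of ribosomal protein genes rpsO was at 3.25 (1.90) and rpmJ at 2.75 (1.53). Of heat shock and envelope stress genes clpX was at 2.24 (0.99), rpoH at 1.94 (0.54) and bamC at 1.99 (0.76), and without 70 kJ/kg replicate 3 rpoH was at 2.91. Of tricarboxylic acid cycle and sugar uptake genes sucA was at 1.88 (0.76), sdhB at 1.58 (0.61), fruB at 1.78 (0.50) and ptsG at 1.64 (0.54). Of iron uptake and fatty acid synthesis genes exbD was at 1.53 (0.55), fhuA at 1.45 (0.40), accC at 1.77 (0.66) and fabG at 1.48 (0.52). Of histidine synthesis and superoxide genes hisD was at 1.27 (0.56), hisG at 0.84 (0.42), acrB at 1.18 (0.31) and marB at 0.72 (0.11). Of 20 toxin-antitoxin genes 1 fell, with 0 higher and 3 lower adjusted over the list alone, and of 22 acid resistance genes 0 fell. In these lists hdeA (-0.65) and mqsR (-0.60) did not pass over all genes tested, nor did gadB (-0.64; -0.38 without 70 kJ/kg replicate 1), uncertain because it shares reads with a near-identical copy.

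At 70 kJ/kg 20 of 4908 tested genes passed limma's test at the adjusted threshold, 5 higher and 15 lower. Of these, 3 changed at least 2-fold. The call count was 0, 1 and 0 without control replicates 1, 2 and 3 and 0 and 0 without 70 kJ/kg replicates 1 and 2. Of the 11 genes named for 70 kJ/kg that passed, 0, 0 and 0 still passed without control replicate 1, 2 or 3 and 0, 0 and 8 without 70 kJ/kg replicate 1, 2 or 3. The count was 1 with only the compared groups, 1287 without the 4 libraries least like their groups, 81 higher and 144 lower after quantile normalization and 1 with scaling to each library's own reads. Between 70 and 50 kJ/kg limma called 0 of 4908 genes, against 542 at an unadjusted p under 0.05 and 0 by voom. The smallest p-values belonged to tauD (-0.55 ± 0.12 SE) and tauC (-0.67 ± 0.16 SE) of taurine use, tsuB (-0.59 ± 0.14 SE), rssA (0.48 ± 0.11 SE) and yaaX (-0.84 ± 0.19 SE), all at adjusted p = 0.401. The count was 328 without 70 kJ/kg replicate 1, 1563 without the 4 libraries least like their groups and 2276 with library weights. Camera called 19 lists, 14 of them lower at 70 kJ/kg, and with an estimated correlation their adjusted p was 0.606 or more.

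**Figure D3:**
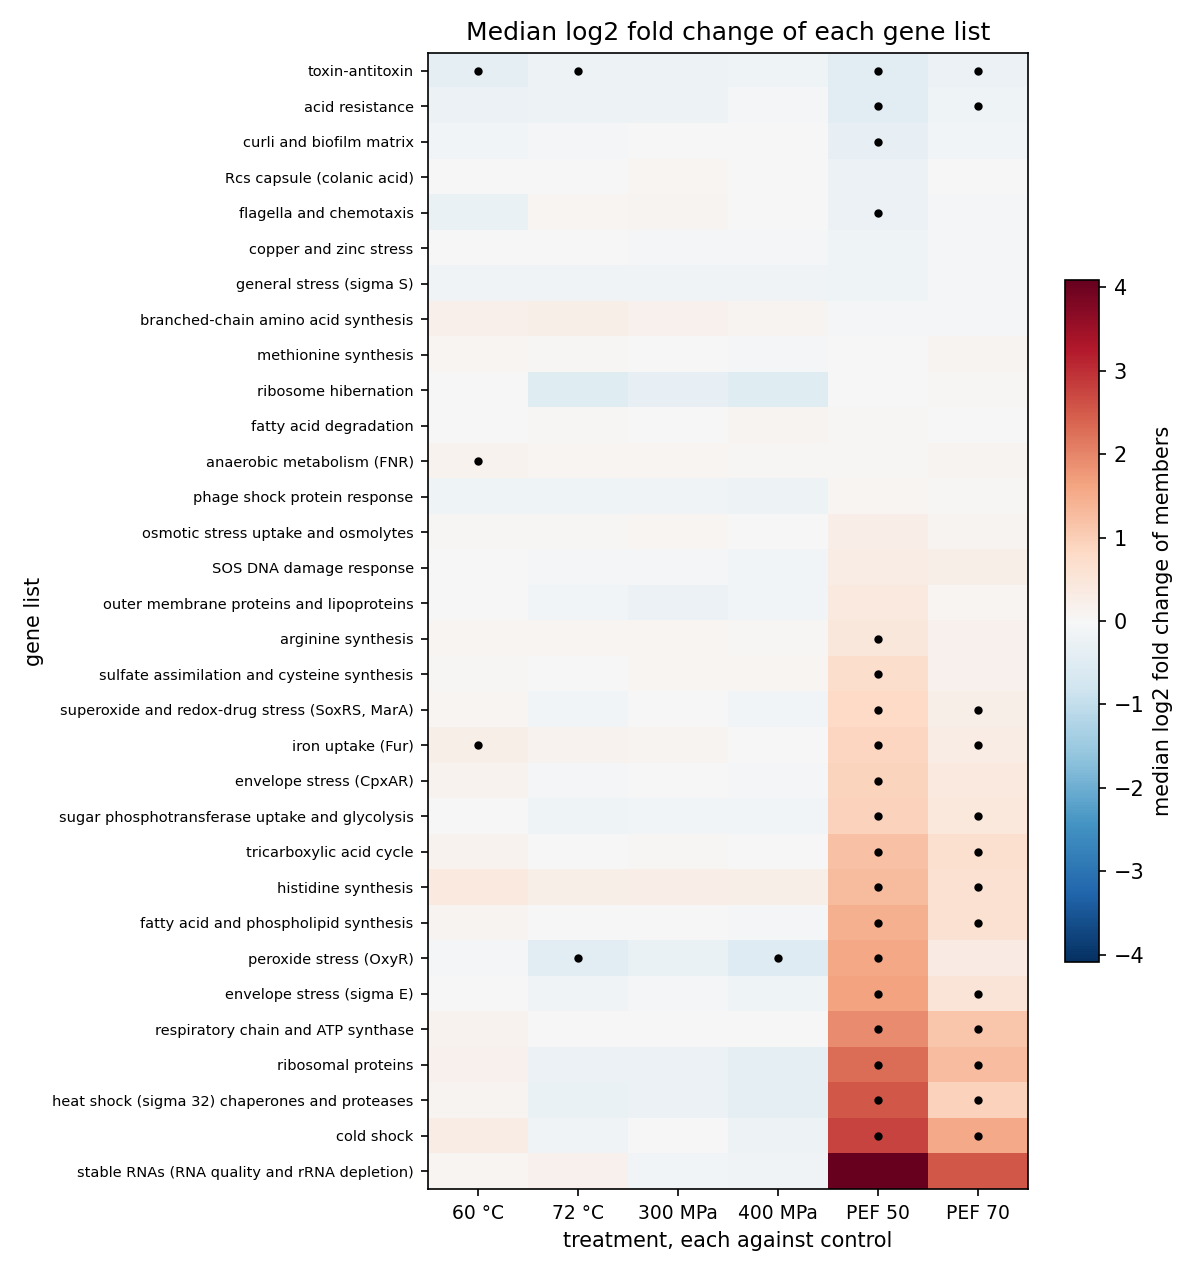
Colour gives the median log2 fold change against control of the members of each of the 32 gene lists (vertical axis) in each treatment (horizontal axis), and a black dot marks an adjusted p under 0.05 by camera with the preset correlation. The 50 kJ/kg column holds the largest medians, 4.09 for the stable RNAs and 2.76 for cold shock. The mean of the cold shock list there was 2.66, and 1.68 without 50 kJ/kg replicate 3.

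In the electric field libraries rnpB took 3.29 to 48.1% of reads, against 0.0587 to 4.25% in the heated ones. Averaged over both intensities, 8 of 12 cold shock genes were higher after pulsed electric fields than after heating, with 11 higher and 0 lower adjusted over the list alone. The list had adjusted p = 5.69e-06 with the preset correlation and adjusted p = 0.468 with an estimated correlation. The cold shock gene cspB was at 17067 ± 21469.6 against 225 ± 57.9 FPKM (SD, n = 6; log2 fold change 5.10 ± 0.66 (SE), adjusted p = 0.00484), the largest difference of a named gene. Without 50 kJ/kg replicate 3 the first mean was 10975 ± 17260.0 FPKM (SD, n = 5). That mean was still carried by 70 kJ/kg replicate 1, at 41803 FPKM. The remaining electric field libraries lay at 2102 to 4768 FPKM. cspB was followed by yrbN (4.60), cspE (4.24), nlpI (4.22) and yhhW (3.35). The phosphonate genes phnJ (-0.62) and phnK (-0.60), and hofO (-0.59), thiS (-0.58) and rhaB (-0.57) were lower. Of 54 ribosomal protein genes 42 were higher, with 50 higher and 0 lower adjusted over the list alone. The list had adjusted p = 3.84e-16 with the preset correlation and adjusted p = 0.468 with an estimated correlation. It was 1 of 18 lists called, of which 0 held with an estimated correlation. In this comparison 947 of 4908 tested genes passed limma's test at the adjusted threshold, 563 higher and 384 lower. Of these, 378 changed at least 2-fold. Among 100 splits of the samples, the real one included, 11 reached 947 genes, so chance was not excluded. The count was 0 with only the 4 compared groups, 658 higher and 1098 lower after quantile normalization, 227 higher and 3213 lower with scaling to each library's own reads and 2170 without the 4 libraries least like their groups. Single libraries moved it to 168 and 211 without 60 °C replicates 2 and 3, 215, 153 and 214 without 72 °C replicates 1, 2 and 3, 1962, 1519 and 609 without 50 kJ/kg replicates 1, 2 and 3 and 283 without 70 kJ/kg replicate 1.

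After high pressure cspB was lower than after pulsed electric fields (log2 fold change -5.33 ± 0.66 (SE), adjusted p = 0.00274). So were lpp (-5.19), ymcF (-4.90), ybiJ (-4.78) and cspE (-4.64). Higher after pressure were hycA (0.51), eutB (0.49), hyfE (0.46), ilvC (0.43) and yehP (0.40). Of these 10 named genes, 2, 9 and 2 still passed without 300 MPa replicate 1, 2 or 3. Without 400 MPa replicate 1, 2 or 3 the numbers were 5, 1 and 3. They were 10, 10 and 7 without 50 kJ/kg replicate 1, 2 or 3 and 5, 10 and 10 without 70 kJ/kg replicate 1, 2 or 3. After pressure rnpB took 0.0604 to 4.72% of reads, against 3.29 to 48.1% after electric fields. Of 54 ribosomal protein genes 45 were lower, with 0 higher and 53 lower adjusted over the list alone. That list had adjusted p = 3.01e-22 with the preset correlation and adjusted p = 0.404 with an estimated correlation, and of 21 lists called 0 held with an estimated correlation. Here 551 of 4908 tested genes passed limma's test at the adjusted threshold, 76 higher and 475 lower. Of these, 369 changed at least 2-fold. Among 100 splits of the samples, the real one included, 9 reached 551 genes, so chance was not excluded. The count was 0 with only the 4 compared groups, 1151 higher and 790 lower after quantile normalization, 3795 higher and 250 lower with scaling to each library's own reads and 1499 without the 4 libraries least like their groups. Dropping 1 library gave 2, 292 and 2 without 300 MPa replicates 1, 2 and 3, 55, 1 and 25 without 400 MPa replicates 1, 2 and 3, 2207, 1426 and 181 without 50 kJ/kg replicates 1, 2 and 3 and 169 and 896 without 70 kJ/kg replicates 1 and 3. Between high pressure and heating limma called 0 of 4908 genes, against 226 at an unadjusted p under 0.05 and 0 by voom, and 695 were called without the 4 libraries least like their groups. The smallest p-values there belonged to thiS (-0.49 ± 0.11 SE), yeeA (0.30 ± 0.07 SE), phnK (-0.47 ± 0.12 SE), hmsP (-0.19 ± 0.05 SE) and ygiL (0.38 ± 0.10 SE), all at adjusted p = 0.758. Of 12 methionine synthesis genes 0 passed, with 0 higher and 0 lower adjusted over the list alone. The list was lower after pressure, with a median of -0.11 and adjusted p = 0.00278 with the preset correlation and adjusted p = 0.0457 with an estimated correlation. It was the only one of 7 lists called here that held with an estimated correlation.

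Several genes changed in the same direction in many treatments. phnC and ygaH rose in all 6, and 11 genes, among them rseD, arfA and yafN, fell in all 6. Leaving out any single compared library lost the phnC call at 72 °C, 300 MPa, 400 MPa and 70 kJ/kg. Its log2 fold changes there stayed at 0.87 to 1.12. The ygaH call at 70 kJ/kg was lost in the same way. In 2 or more treatments 69 genes rose and 158 fell, 227 in total. In 100 simulations of unchanged groups against shared controls the mean was 59.9, the median 0 and the highest value 1614. Fold changes of the 4 heat and pressure treatments correlated pairwise at 0.455 to 0.905 across genes, which are not independent replicates. In the simulations these pairs correlated at 0.170 to 0.521 on average. In correlation, though not in covariance, some pairs with an electric field lay below their simulated values. They were 400 MPa with 50 kJ/kg (0.0953 against 0.220 simulated), 72 °C with 50 kJ/kg (0.199 against 0.222) and 400 MPa with 70 kJ/kg (0.260 against 0.277). The covariances of these pairs, in the same order, were 0.0316, 0.0654 and 0.0469 against 0.00896, 0.00901 and 0.00936 simulated. The remaining pairs lay above their simulated correlations. The most correlated of the heat and pressure pairs, 72 °C and 400 MPa, shared 12 raised and 27 lowered genes, where independent lists of those sizes would share 0.0866 and 0.342 and the simulations shared 0.0200 on average. Its correlation was 0.521 in the simulations, and it had a covariance of 0.105 against 0.00823. The 3 control libraries were not split between treatments, so part of the excess may come from the shared controls. The number of shared genes was 54, 58 and 52 without control replicates 1, 2 and 3. None of the 626 log2 fold changes called in the 227 genes then fell below 0.745 times its value, in genes picked with all 3 controls. The 12 gene lists that camera called in no treatment, among them the general stress, SOS, phage shock and osmotic stress lists, had adjusted p-values of 0.0546 or more in the 6 treatments. The stable RNA list was one of these, although its 4 members had a median of 4.09 at 50 kJ/kg, where 1 of them rose (adjusted p = 0.132), and of 2.54 at 70 kJ/kg (adjusted p = 0.0817).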

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

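Scaling to each library's own reads and leaving out the libraries least like their groups were chosen after the data were seen. Dropping the noisiest libraries by rule lowers the spread by itself. Both pseudocounts, no filter, the stricter filter and median-of-ratios rescaling left each of the 12 gene counts within 1.5 times its value; the rescaling moved nothing because the values already carried equal factors. Counts moved by more than 1.5 times under the alternatives below, and the cause was not tested.

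Quantile normalization gave 848 for 60 °C, 369 for 72 °C, 290 for 300 MPa, 297 for 400 MPa, 225 for 70 kJ/kg, 1756 for electric field against heating, 1941 for pressure against electric field. With only the compared groups in the fit the counts were 2619 for 72 °C, 1241 for 300 MPa, 2537 for 400 MPa, 1 for 50 kJ/kg, 1 for 70 kJ/kg, 0 for electric field against heating, 0 for pressure against electric field. Library weights gave 3080 for 60 °C, 2887 for 72 °C, 2506 for 300 MPa, 2869 for 400 MPa, 2823 for 50 kJ/kg, 2504 for 70 kJ/kg, 544 for 72 against 60 °C, 2276 for 70 against 50 kJ/kg, 1590 for pressure against heating, 2476 for electric field against heating, 2164 for pressure against electric field. Requiring a 2-fold change left 46 for 60 °C, 3 for 72 °C, 7 for 300 MPa, 6 for 400 MPa, 642 for 50 kJ/kg, 3 for 70 kJ/kg, 378 for electric field against heating, 31 for shared genes. voom on recovered reads gave 506 for 60 °C, 257 for 72 °C, 225 for 300 MPa, 205 for 400 MPa, 101 for 70 kJ/kg. Scaling to each library's own reads gave 0 for 60 °C, 0 for 72 °C, 0 for 300 MPa, 0 for 400 MPa, 3416 for 50 kJ/kg, 1 for 70 kJ/kg, 3440 for electric field against heating, 4045 for pressure against electric field, 58 for lists called in the 6 treatments, 1 for shared genes. Leaving out the 4 libraries least like their groups gave 2449 for 60 °C, 2132 for 72 °C, 1873 for 300 MPa, 2100 for 400 MPa, 2850 for 50 kJ/kg, 1287 for 70 kJ/kg, 1563 for 70 against 50 kJ/kg, 695 for pressure against heating, 2170 for electric field against heating, 1499 for pressure against electric field, 2768 for shared genes. The number of list calls in the 6 treatments against control was 38, against 0 with an estimated correlation and 21 by fry's directional test. Of the 38 list calls, 16 held by fry's directional test and 25 with scaling to each library's own reads.

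When each compared library was left out in turn, the counts ranged from 71 to 478 for 60 °C, from 2 to 15 for 72 °C, from 6 to 19 for 300 MPa, from 6 to 19 for 400 MPa, from 638 to 2703 for 50 kJ/kg, from 0 to 19 for 70 kJ/kg, from 0 to 0 for 72 against 60 °C, from 0 to 0 for 400 against 300 MPa, from 0 to 328 for 70 against 50 kJ/kg, from 0 to 0 for pressure against heating, from 153 to 1962 for electric field against heating, from 1 to 2207 for pressure against electric field.

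Replicate numbers were not shown to pair the samples, but pairing was not excluded. Deviations of same-numbered libraries correlated from -0.849 to 0.623, with a mean of 0.0122 against 0.00373 for other numbers. Of 21 libraries, 10 correlated best with their own number. With the replicate number as a block the counts were 228 for 60 °C, 30 for 72 °C, 32 for 300 MPa, 45 for 400 MPa, 1363 for 50 kJ/kg, 0 for 70 kJ/kg, 634 for electric field against heating, 302 for pressure against electric field, and 0 for the other comparisons.

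At 70 kJ/kg the heat shock list had a mean log2 fold change of 0.0207, the sigma E list -0.000265, the superoxide list -0.0472 and the sugar uptake list -0.0313 both without 70 kJ/kg replicate 1 and without the 4 libraries, and the acid resistance list -0.0752 without the 4 libraries. Relative to the other genes these lay on the opposite side. The highest means with 1 library left out were 1.36, 1.08, 0.463 and 0.812 for the first 4 of these lists, without 70 kJ/kg replicate 3. With scaling to each library's own reads carB at 50 kJ/kg was at -0.0699 and ygaH at 70 kJ/kg at -0.10; that scaling moved the median gene by -1.54 and -0.71 at these energies. Of the named genes, the side of the threshold was kept by 179 of 179 with a pseudocount of 5, 163 of 179 by voom and 85 of 179 with only the compared groups. Depth limited 60 °C replicate 1 most, with 704174 reads.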

Other observations

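In replicates 1, 2 and 3 the stable RNA rnpB took, of the reads, 4.25, 0.269 and 0.0587% at 60 °C, 1.76, 0.546 and 2.62% at 72 °C, 0.169, 4.72 and 0.388% at 300 MPa, 2.08, 0.0604 and 4.37% at 400 MPa, 10.3, 25.3 and 48.1% at 50 kJ/kg, 39.6, 6.73 and 3.29% at 70 kJ/kg and 1.71, 0.545 and 1.56% in control libraries. The transfer-messenger RNA ssrA took 5.47, 0.581 and 0.0866% at 60 °C, 0.193, 0.0332 and 0.355% at 72 °C, 0.233, 1.91 and 0.349% at 300 MPa, 0.278, 0.0103 and 0.128% at 400 MPa, 3.55, 5.86 and 2.22% at 50 kJ/kg, 6.32, 1.28 and 0.606% at 70 kJ/kg and 1.17, 0.302 and 1.08% in control libraries. The ratio of the ribosomal protein median to the curli median was 2.33, 1.35 and 0.985 at 60 °C, 0.983, 0.872 and 0.997 at 72 °C, 0.831, 1.30 and 0.889 at 300 MPa, 0.844, 0.763 and 0.800 at 400 MPa, 3.34, 3.38 and 27.8 at 50 kJ/kg, 12.6, 1.42 and 1.08 at 70 kJ/kg and 1.39, 1.01 and 1.37 in control libraries. These shares were picked after their values were seen and were not tested between groups.

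The tests below were chosen after the results were seen, except the simulation of all 6 treatments and the splits of the samples. Most genes lay near 1 level in most libraries. Loss of transcripts through the treatments was argued against, because the untreated control libraries showed the pattern too, with 90.2% or more of genes within 2-fold of the median. A candidate explanation is genomic DNA in the libraries: the ribosomal protein to curli ratio had a median of 1.37 in the controls, where DNA would give a value near 1. No reads or genome were used here, so this stays a hypothesis.

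The transcripts raised at 50 kJ/kg, taken without the stable RNAs, moved with rnpB. Per 1000 FPKM of rnpB they exceeded the library median on average by 0.384 to 0.986 FPKM in the 6 electric field libraries. In the 8 other libraries with at least 30000 FPKM of rnpB this excess was 0.209 to 1.47 FPKM. The ratio of medians was 1.21, and the 7 libraries with less rnpB lay at -1.11 to 5.74. More RNA over a constant level may account for the rises as a group. Its makeup was not unchanged, since ssrA did not keep step with rnpB. At 50 kJ/kg ssrA had 105129, 255369 and 469513 FPKM beside 292170, 1061115.5 and 9785128 of rnpB. In control libraries it had 26447, 6471 and 24489 beside 37367, 11242 and 34028. The makeup was not alike in all libraries: the excess of ribosomal proteins was 0.610 to 2.35 in the electric field libraries and 1.26 and 1.43 in control libraries, but -0.246 to 0.104 at 72 °C and 400 MPa, 0.602 in 300 MPa replicate 2, 3.16 in 60 °C replicate 1 and -30.2 to 2.63 in the libraries with less rnpB. For cspB, picked as the top gene of the contrast, the values do not decide: its excess was 1.81 to 39.4 in the electric field libraries and -0.186 to 1.39 in the 6 heated or pressure-treated ones above that level of rnpB (ratio of medians 15.1), but the 6 below it, at 2.29 to 8.56, and the control libraries, at 3.53 to 9.78, lay inside the electric field range. A list fixed beforehand, the ribosomal protein genes, argues against replicate 3 of 50 kJ/kg alone making the rises, for these genes. Their median was 494 and 473 FPKM in replicates 1 and 2, against 207, 154 and 204 FPKM in control libraries. For the 879 raised genes leaving out replicate 3 cannot decide this, because they were picked with all 3 treated libraries in the test. Without replicate 3 all 879 lay above 0. They had a median log2 fold change of 0.72 (quartiles 0.44 and 1.29) instead of 1.30 (0.77 and 2.15). At these lower folds 220 were called with the spread of all other libraries. The number was 873 once the other 3 libraries least like their groups were left out too, which lowers the spread by itself. Scaling to each library's own reads moved the median gene by -1.54 on the log2 scale at 50 kJ/kg, so its count of raised genes cannot test the authors' scaling, which stays open, as does a response of the cells to the field.

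For all 6 treatments the simulation cannot decide whether genes called in several treatments came from the shared controls. In 6 of 100 simulations at least 227 genes were shared, although the median was 0. The highest count of 1614 came from the pair of electric fields, whose groups held libraries unlike their replicates. A simulation can draw such a library's deviation more than once, which shifts a treated group without the controls. For the heat and pressure treatments alone, 84 genes were shared and 0 simulations reached that number, the highest giving 39, which argues against the shared controls alone for that part. Leaving out 1 control library cannot decide whether it alone made the shared calls. The genes were picked with all 3 controls in the test, which favours genes whose controls agree. Without each in turn, their 626 log2 fold changes had a median ratio of 0.995 or more to the values with all 3. The lowest ratio was 0.745, and 352 to 377 of these calls were lost. The totals were 54, 58 and 52 shared genes without control replicates 1, 2 and 3, with 2 control libraries in the test. A difference between control and treated libraries in handling was not tested.

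Other splits of the samples were compared with the real ones. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real and the highest other counts were 310 and 0 for 60 °C, 65 and 0 for 72 °C, 64 and 1 for 300 MPa, 59 and 0 for 400 MPa, 1673 and 0 for 50 kJ/kg, 20 and 1 for 70 kJ/kg, 0 and 0 for 72 against 60 °C, 0 and 0 for 400 against 300 MPa, 0 and 2645 for 70 against 50 kJ/kg. As many genes as the real split came from 1, 1, 1, 1, 1, 1 splits for the treatments against control in that order, and from 10, 10, 10 for the pairs of intensities, where any split reaches a count of 0 and the test says nothing. The split of the electric field libraries that called 2645 genes points to a structure of the samples other than the energy. With 6 against 6, 11 of 100 splits drawn reached the real count of 947 for electric field against heating (highest other 1811) and 9 of 100 the 551 for pressure against electric field (highest other 1776), so chance was not excluded for these 2. For pressure against heating the real count was 0, which 100 of 100 splits reach by construction (highest other 0), so this test says nothing there.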
